A study of Mus musculus with 8 samples.

How the data were processed

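Expression was measured on 8 arrays of mouse whole embryos, 4 of 8-cell embryos and 4 of blastocysts. Per the labels' protocols, embryos were cultured in KSOM medium, RNA was isolated with a small-sample column kit and amplified with a labelling assay meant for small samples, and biotin-labelled RNA was made from it for hybridisation. The deposited values are signal intensity on a linear scale for 45101 probe sets, and the software that made them is not given in the sources used here. The values themselves show that each array had been scaled to the same mean (500 after removal of the outer 2%). All values of the 8-cell columns have at most 1 decimal, which holds for under 0.4% of the values of each blastocyst column. No detection calls or scan dates were used here.

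Samples were grouped by the stage in their titles. Values became log2(signal + 16). The array medians on that scale differed by less than 0.5 between the highest and the lowest array, so by the rule set before the data were examined the deposited scale was kept. The table held 64 control probe sets, which stayed out of the gene tests. The platform's annotation gave 1 gene symbol to 34958 probe sets, several to 932, and did not list 9160 others, which are unnamed here. Probe sets with several symbols named no gene. Gene IDs were looked up in a reference gene table of the assembly GRCm38.p6, which changed 0 symbols. Of 684 listed gene names 85 matched no probe set with a single symbol. Where a gene had several probe sets (9009 of 18194 genes), the one with the highest mean log2 value was used. Of the called genes 4618 had other probe sets past the filter, and 632 of these had a probe set called in the opposite direction. Genes above the 40th percentile of the array on at least 4 of the 8 arrays, 13274 in all, were tested. Among called genes, 338 higher genes had all 8-cell arrays under that level, and 333 lower genes had all blastocyst arrays under it. Folds are on the log2(signal + 16) scale and understate the change of dim genes.

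The comparison was blastocyst minus 8-cell with limma (lmFit and eBayes with default settings, no covariates) and Benjamini-Hochberg adjustment, with a threshold of 0.05. The number of genes changed at least 2-fold was counted beside it. In all, 26 gene lists (junctions, polarity, transport, lineage markers, maternal and early zygotic genes, metabolism, ribosomes, cell cycle, stress, imprinting, membrane traffic and markers of other cells) were fixed before the data were examined. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. With an estimated correlation, camera also takes its degrees of freedom from the 8 arrays and no longer from the tested genes. It can then call less even where the genes of a list do not vary together. The named genes follow a rule fixed before the data were examined. It takes Tfap2c, the 12 genes with the highest and the 12 with the lowest difference among called genes with non-overlapping stages (probe set IDs ending in _x_at, and symbols ending in Rik or made of Gm or LOC and a number, left out; the clone-derived name BC053393 has none of these forms and stayed in), the 4 called members with the largest differences in each list, and 20 fixed genes. Genes outside this rule are said to have been named after their values were seen. Array quality was compared by exact two-sided permutation tests over the 70 assignments of the arrays.

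The method was tested on simulated data with 13274 genes, 4 against 4 arrays and 200 changed genes in each of 20 runs. It recovered 12.6% of the changes of 0.5 log2 units, 61.7% of those of 1 and 91.4% of those of 2, and 5.08% of its calls were false. A shifted list of 25 genes was called by camera in 20 of 20 runs and a list without a shift in 1. Noise was drawn separately for each gene, so the runs do not show how camera behaves when genes of a list vary together. In the real data 71.7% of the tested genes were called, so the shares recovered here need not hold there.

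The alternatives were quantile or median scaling, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets whose IDs end in _x_at, _s_at or _a_at, an intensity trend with robust estimation, array weights, a replicate block, an added 1 or 64 in place of 16, and leaving out each array. The mean of a gene's probe sets also takes in those under the filter, so dim probe sets can shrink a difference. Scaling to the bacterial hybridisation spike-ins was added after the data were seen. Each alternative changed 1 choice and kept the tested genes and their probe sets, unless the filter or the probe sets were the choice. That last rule was set after a first run had been seen in which the filter was repeated at each left-out array. The analysis used R 4.3.3, limma 3.58.1 and the data.table package (1.17.8), and the plots Python 3.11.15 and matplotlib 3.10.9.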

Results

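Messenger RNA of whole mouse embryos was measured at 2 stages of preimplantation development with 1-colour oligonucleotide arrays. The stages were the 8-cell embryo (embryonic day 2.5, 66 h after human chorionic gonadotropin, the hormone given to time ovulation) and the blastocyst (day 4.5, 120 h), the hollow embryo with an outer epithelium around a fluid-filled cavity. Each stage had 4 arrays. They read whole embryos, so a change in the share of a cell type cannot be told apart from a change within cells. The embryos were wild type, from matings of B6D2F1 females and males, and had been cultured from the 1-cell stage. The series title names the transcription factor AP-2 gamma (Tfap2c), tight junctions and cavity formation, so the comparison of the stages asks which genes change while the embryo forms its epithelium and cavity. Differences are given as blastocyst minus 8-cell on the log2(signal + 16) scale with the standard error (SE), signals as mean ± SD of the 4 arrays of a stage, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named. Signals were scaled per array, so rises and falls are relative to the other signals of an array and are not amounts per embryo. The number of arrays limits the precision. Nothing in the labels says that the 4 arrays of a stage came from separate pools of embryos, so p-values measure the spread between these samples, which may be technical.

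The deposited signals had been scaled so that the mean signal after removal of the outer 2% was 500 on each array, and the array medians lay between 47.1 and 56. Arrays of the same stage correlated over the 13274 tested genes at 0.977 to 0.981 (8-cell) and 0.982 to 0.988 (blastocyst), and arrays of different stages at 0.752 to 0.780. The first principal component held 89.0% of the variance and separated the stages, and the second held 2.34%. The RNA had been amplified from few cells, and the control probe sets at the 3' and 5' ends of a transcript differed more on the 8-cell arrays. For Actb the 3' minus 5' difference was 2.42 ± 0.19 log2 units in 8-cell embryos and 0.82 ± 0.11 in blastocysts, and for Gapdh 2.32 ± 0.26 and 1.36 ± 0.11 (SD, n = 4 each; exact two-sided permutation test, p = 0.0286 for each, the smallest that 4 against 4 arrays can give; adjusted p = 0.0571 over 6 measures of array quality). The interquartile range of the log2 signals was 3.37 ± 0.03 and 3.73 ± 0.04 (p = 0.0286 by the same exact test, adjusted p = 0.0571). The median log2 signal (6.12 and 6.06, exact permutation p = 0.343), the bacterial hybridisation controls (11.73 and 11.47, p = 0.171) and the share of signal on the 100 brightest probe sets (7.39% and 6.70%, p = 0.143) did not pass this exact test. The 8-cell columns of the value table carry 1 decimal on all values and the blastocyst columns do not, so any difference in how the arrays of a stage were handled cannot be told apart from the stage itself.

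**Figure D1:**
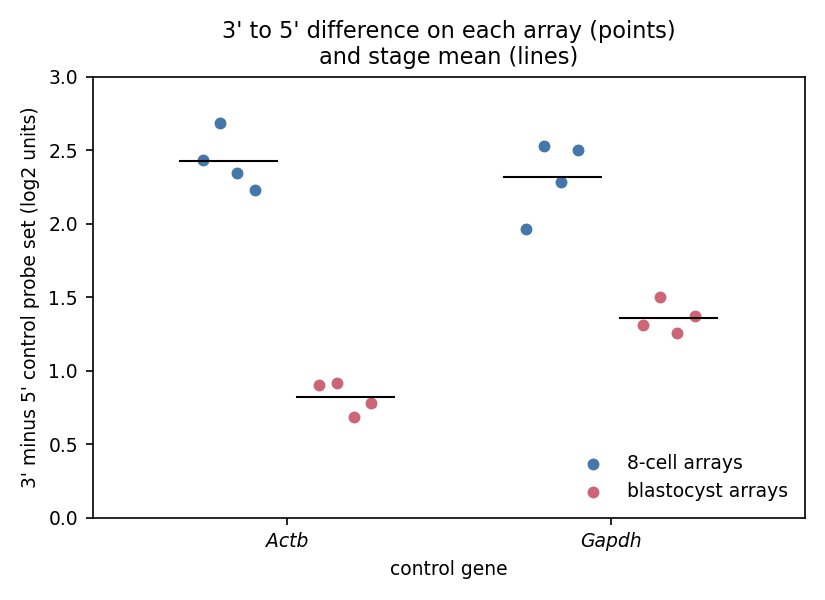
Difference between the 3' and the 5' control probe set of Actb and Gapdh in log2 units (vertical axis) for each array (points, 4 per stage), with the stage mean as a line. The 8-cell arrays average 2.42 for Actb and 2.32 for Gapdh, and the blastocyst arrays 0.82 and 1.36.

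Between the 8-cell embryo and the blastocyst, genes of trophectoderm, primitive endoderm, junctions, oxidative phosphorylation and cholesterol synthesis rose as groups, and genes of the oocyte, of zygotic genome activation and of ribosome assembly fell, by camera with a preset correlation. None of the 10 lists called this way passed with an estimated correlation (adjusted p = 0.104 to 0.651), and tight junction genes did not pass with a filter at the 60th percentile (adjusted p = 0.0533). Among single genes the largest rises on the log2(signal + 16) scale were those of Adh1, an alcohol dehydrogenase (392-fold, log2 difference 8.62, SE 0.12), Elf5, a transcription factor of trophoblast (330-fold, 8.37, SE 0.15), and Lgals1, the lectin galectin-1 (278-fold, 8.12, SE 0.21). With 1 added in place of 16 the order changed, and Elf5 (10.43), Gjb5 (9.60) and Dmkn (9.175) stood above Adh1 (9.11). The largest falls were those of the forkhead factor Foxa1 (245-fold lower, log2 difference -7.94, SE 0.28) and of Exoc3l2 (132-fold lower, -7.05, SE 0.32). Exoc3l2 gave -3.45 with the mean of its probe sets, which takes in probe sets under the filter. Of 13274 genes tested, 4978 were higher and 4539 lower in blastocysts at an adjusted p under 0.05, together 71.7% of the genes. A change of at least 2-fold was found for 3368 higher and 2712 lower genes. In 8870 genes (66.8%) the 4 values of one stage lay entirely above those of the other, against 2.86% by chance. With the arrays scaled to their hybridisation spike-ins, an alternative chosen after the data were seen, the median difference of the tested genes moved from 0.02 to 0.26, and 5403 genes were higher and 3244 lower, so that 62.5% of the calls were higher against 52.3% on the deposited scale.

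The other genes with the largest rises, all with adjusted p of 2.52e-07 or less, were Tmprss2, a membrane serine protease (8.03, SE 0.35), B3gnt5, a glycosyltransferase (7.95, SE 0.25), Dmkn (7.64, SE 0.33), Tceal9 (7.58, SE 0.41), Gjb5, a gap junction connexin (7.53, SE 0.11), Slc15a2, a peptide transporter (7.48, SE 0.16), Tmsb4x, the actin-binding thymosin beta 4 (7.45, SE 0.19), BC053393 (7.33, SE 0.17) and Tpp1, a lysosomal peptidase (7.31, SE 0.38). Adh1 went from 35.6 ± 3.81 to 20233 ± 1802 and Lgals1 from 87.3 ± 28.2 to 27829 ± 1993. The other largest falls were those of Tnfsf13b, a cytokine of the tumour necrosis factor family (-6.91, SE 0.11), Bex6 (-6.83, SE 0.24), Acsl4, an acyl-CoA synthetase (-6.67, SE 0.29), Klf17, a zinc finger factor (-6.66, SE 0.20), Arg1, an arginase (-6.48, SE 0.12), Omt2b (-6.40, SE 0.21), the coactivator Cited1 (-6.30, SE 0.30), Tmem267 (-6.23, SE 0.22), Cthrc1 (-6.20, SE 0.23) and Pfkfb3, a regulator of glycolysis (-6.09, SE 0.28). With the mean of a gene's probe sets Tnfsf13b gave -4.20, Acsl4 -4.33, Pfkfb3 -3.50, Tmprss2 5.15, B3gnt5 5.35 and Elf5 6.32, which put Elf5 below Lgals1, Slc15a2, Dmkn, Tceal9, Gjb5, Tmsb4x and BC053393. Klf17 fell from 12913 ± 1811 to 114 ± 30.0. The 8-cell signals of Elf5, B3gnt5, Dmkn and Gjb5, and the blastocyst signals of Exoc3l2, Arg1, Omt2b, Tmem267 and Pfkfb3, lay in the lower part of each array, under its 40th percentile, so their folds and ranks depend on the added 16. The same holds in part for Foxa1 in blastocysts (20.9 ± 12.8) and Tpp1 in 8-cell embryos (29.4 ± 30.6), with 1 of 4 arrays above that level, for Tnfsf13b, Bex6 and Cthrc1 in blastocysts (2 of 4), and for Tmprss2 and Tceal9 in 8-cell embryos and Acsl4 and Cited1 in blastocysts (3 of 4). Foxa1 gave -9.03 with 1 added and -6.67 with 64 added. Some genes named from the lists below were also under that level on each array of a stage, so their sizes depend on the added 16. Among those named by the rule, these were Dsc2, Sox17, Lama1, Rab25, Thy1 and Pdgfrb in 8-cell embryos, and Nlrp14, Oosp1 and Flt1 in blastocysts. Above that level on 1 of 4 arrays were Cldn3, Sparc, Cited4, Casp9, Lyz2 and Rhox6 in 8-cell embryos and Spz1 in blastocysts. Hspa1a was above it on 2 of 4 blastocyst arrays. On 3 of 4 were Aqp8, Plac1, Gata2, Sox2, Serpinh1 and Mbd2 in 8-cell embryos and Kctd14 and Cd52 in blastocysts. Their sizes depend in part on the added 16.

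Tfap2c was lower in blastocysts. Its brightest probe set gave 7316 ± 1079 in 8-cell embryos and 2988 ± 306 in blastocysts, 2.43-fold lower (log2 difference -1.28, SE 0.14, adjusted p = 2.63e-05). The 4 blastocyst arrays were each below the 4 8-cell arrays. The other probe sets of the gene, tested among all probe sets, gave -1.04 (SE 0.14, adjusted p = 7.58e-05) and -0.71 (SE 0.26, adjusted p = 0.0362). Its relative Tfap2a went the other way, from 136 ± 55.9 to 3691 ± 305 (4.67, SE 0.22, adjusted p = 1.24e-07), and Tfap2e fell by 1.89 (SE 0.16). Of 9 tested members of the TFAP2 family and its cofactors 4 were higher, among them Cited4 (2.85, SE 0.45, or 1.16 with the mean of its probe sets), 3 were lower, among them Cited1, and 2 did not pass. The counts adjusted over the list alone were also 4 and 3. As a list they did not pass (camera, adjusted p = 0.999; 0.999 with an estimated correlation), with a median of 0.48 and a mean of -0.07.

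**Figure D2:**
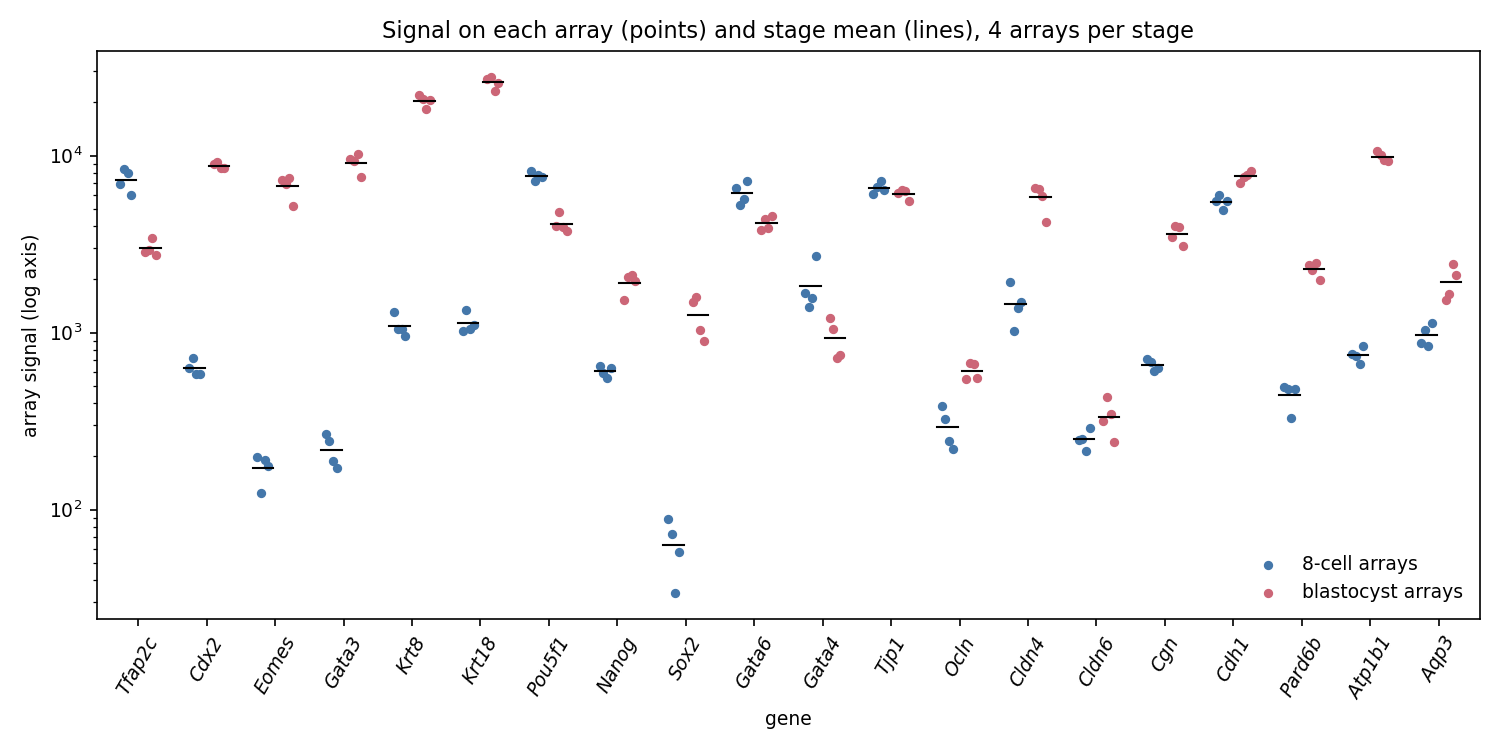
Signal (vertical log axis, arbitrary units) of Tfap2c and 19 genes chosen before the data were examined, on each of the 4 arrays per stage (points), with stage means as lines. Tfap2c, Pou5f1, Gata6 and Gata4 were lower in blastocysts on the deposited scale, Gata6 not passing under hybridisation spike-in scaling, and Tjp1 (6551 and 6080) and Cldn6 (251 and 335) did not pass the test.

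Tight junctions seal the outer epithelium of the blastocyst. Of 23 tested tight junction genes 13 were higher, 2 were lower and 8 did not pass (13 and 2 adjusted over the list alone). Cldn3, a claudin, rose from 26.7 ± 16.8 to 2618 ± 366 (6.02, SE 0.26), the paracingulin gene Cgnl1 rose by 4.60 (SE 0.16), Lsr, a protein of tricellular junctions, by 4.59 (SE 0.27) and the scaffold gene Tjp3 by 3.97 (SE 0.12). With the mean of a gene's probe sets Cgnl1 gave 1.84 and Lsr 2.26. Smaller rises were those of Cgn, encoding cingulin (2.43, SE 0.13), Cldn4 (2.00, SE 0.22) and Ocln, encoding occludin (1.04, SE 0.18, adjusted p = 0.000539). Tjp1, encoding the scaffold ZO-1, was at 6551 ± 467 and 6080 ± 381 (-0.11, SE 0.11, adjusted p = 0.413), and Cldn6 differed by 0.37 (SE 0.18, adjusted p = 0.0876), with adjusted p under 0.05 in 3 of 20 alternative settings. The lower genes, named after their values were seen, were Tjap1 (-1.02, SE 0.15) and Ybx3 (-0.36, SE 0.13). The list was higher as a group (camera, median 1.04, adjusted p = 0.0232), but not with an estimated correlation (adjusted p = 0.144) or with a filter at the 60th percentile (adjusted p = 0.0533). The estimated correlation of -0.013 lay below the preset 0.01, so correlation among the list's genes does not account for the weaker result.

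Adherens junctions and desmosomes join neighbouring epithelial cells. Of 19 tested genes 13 were higher, 1 was lower and 5 did not pass (13 and 1 adjusted over the list alone). The desmosomal cadherins Dsc2 and Dsg2 rose by 5.65 (SE 0.24) and 5.62 (SE 0.18), the adhesion molecule Epcam by 4.58 (SE 0.12) and the desmosomal plaque gene Pkp2 by 4.43 (SE 0.25). Cdh1, encoding E-cadherin, was already at 5497 ± 460 in 8-cell embryos and rose to 7614 ± 472 (0.47, SE 0.11, adjusted p = 0.00438). The lower gene was Nectin3 (-1.24, SE 0.17), named after its value was seen. The group was higher (camera, median 0.71, adjusted p = 0.00422), with an adjusted p = 0.104 with an estimated correlation. That correlation, 0.0075, also lay below the preset 0.01.

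Cell polarity genes were split. Of 22 tested genes 13 were higher, 7 lower and 2 did not pass (13 and 7 adjusted over the list alone). Msn, encoding the actin linker moesin, rose by 5.85 (SE 0.20), the scaffold genes Patj and Dlg1 by 4.29 (SE 0.16) and 2.38 (SE 0.17), and Pard6b, encoding a partner of atypical protein kinase C, by 2.32 (SE 0.16). Prkci, encoding such a kinase, rose by 2.89 (SE 0.11) on its brightest probe set, but a probe set of another type gave -0.06 (adjusted p = 0.83). With the mean of a gene's probe sets Patj gave 2.17, Prkci 1.42 and Dlg1 1.55. The lower genes included Crb3 (-1.74, SE 0.18) and Pard3b (-1.37, SE 0.15), named after their values were seen. The list did not pass as a group (camera, median 0.71, adjusted p = 0.154; 0.287 with an estimated correlation). Among 17 tested genes of ion and water transport, the process that moves fluid into the cavity, 8 were higher, 7 lower and 2 did not pass, and 9 and 7 were called when adjusted over the list alone. The water channel gene Aqp8 rose by 4.88 (SE 0.40), the sodium pump subunit gene Atp1b1 by 3.69 (SE 0.12), Clic1 by 3.50 (SE 0.19), the anion exchanger gene Slc4a2 by 3.05 (SE 0.24) and the water channel gene Aqp3 by 0.97 (SE 0.18, from 971 ± 139 to 1939 ± 426). Among the lower genes, named after their values were seen, were the cotransporter gene Slc12a2 (-2.91, SE 0.11), the water channel gene Aqp11 (-2.34, SE 0.23) and the sodium pump subunit genes Atp1b3 (-1.19, SE 0.11) and Atp1b2 (-1.06, SE 0.22). This list did not pass as a group either (median 0.63, adjusted p = 0.499; 0.547 with an estimated correlation).

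Trophectoderm markers, the genes of the outer lineage that later forms placenta, rose. Of 29 tested genes 23 were higher, 5 lower and 1 did not pass (23 and 5 adjusted over the list alone), with a median of 4.21. Beside Elf5, Id2 rose by 6.45 (SE 0.18), Plac1 by 6.30 (SE 0.26) and Gata2 by 5.84 (SE 0.13). Without the probe sets whose IDs end in _x_at, _s_at or _a_at, Id2 gave 4.09. The transcription factor genes Gata3, Eomes and Cdx2 rose by 5.30 (SE 0.17), 5.17 (SE 0.18) and 3.78 (SE 0.12), and the keratins Krt18 and Krt8 by 4.51 (SE 0.13) and 4.21 (SE 0.13), to 25971 ± 2068 and 20384 ± 1571. The 5 lower genes were Hand1 (-5.21, SE 0.45), Tead4 (-2.03, SE 0.13), Ascl2 (-1.46, SE 0.22), Tfap2c and Esx1 (-1.23, SE 0.24), of which all but Tfap2c were named after their values were seen. The group shift had an adjusted p = 4.99e-06 by camera and an adjusted p = 0.104 with an estimated correlation.

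Primitive endoderm markers, of the inner lineage that later lines the yolk sac, also rose, with 17 of 20 tested genes higher, 2 lower and 1 not passing (17 and 2 adjusted over the list alone). The matrix protein gene Sparc rose by 7.24 (SE 0.52, or 4.54 with the mean of its probe sets), the transcription factor gene Sox17 from 10.6 ± 4.48 to 3363 ± 319 (SE of the log2 difference 0.15), the laminin chain gene Lama1 by 6.19 (SE 0.19) and the collagen chaperone gene Serpinh1 by 5.02 (SE 0.29). The lower genes were the factors Gata4 (-0.95, SE 0.24, from 1832 ± 584 to 932 ± 234) and Gata6 (-0.55, SE 0.14, from 6156 ± 868 to 4166 ± 369). Gata6 gave -0.29 with hybridisation spike-in scaling (adjusted p = 0.304). The list had a median of 3.44 and an adjusted p = 1.50e-05 by camera, with an adjusted p = 0.251 with an estimated correlation. Epiblast and pluripotency markers did not shift together. Of 24 tested genes 10 were higher, 9 lower and 5 did not pass (10 and 9 adjusted over the list alone; median 0.25, camera adjusted p = 0.874; 0.986 with an estimated correlation). L1td1 rose by 4.39 (SE 0.23), Sox2 by 4.01 (SE 0.26), Tfcp2l1 by 3.34 (SE 0.32), Gdf3 by 2.82 (SE 0.24) and Nanog by 1.63 (SE 0.14), and Pou5f1, encoding OCT4, fell by 0.90 (SE 0.12), from 7671 ± 401 to 4123 ± 455. Tfcp2l1 gave 1.19 with the mean of its probe sets.

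Oocyte and maternal-effect genes, listed for expression or roles in the egg, fell. The arrays do not tell transcripts stored in the egg from those made by the embryo. Of 23 tested genes 19 were lower, 2 were higher and 2 did not pass (19 and 2 adjusted over the list alone; median -2.97, camera adjusted p = 1.50e-05; adjusted p = 0.153 with an estimated correlation). Beside Omt2b, the homeobox gene Obox6 (-5.82, SE 0.20, from 18804 ± 1890 to 326 ± 93.4), Nlrp14 (-4.46, SE 0.26) and Oosp1 (-4.29, SE 0.31) fell most. The higher genes, named after their values were seen, were Ooep (4.20, SE 0.16, from 246 ± 22.4 to 4846 ± 992) and Khdc3 (1.72, SE 0.16, from 5373 ± 1163 to 17442 ± 1348), which encode proteins of the egg's subcortical maternal complex. All 11 tested genes of zygotic genome activation and the 2-cell stage were lower (11 adjusted over the list alone; median -3.19, camera adjusted p = 2.29e-05; adjusted p = 0.104 with an estimated correlation). The largest falls were those of Spz1 (-5.31, SE 0.30), Sp110 (-5.28, SE 0.21), Zfp352 (-4.35, SE 0.28) and Usp17la (-4.17, SE 0.20). Of the 25 listed genes 13 had no probe set with a single matching symbol, so these are not analysed here.

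Hippo pathway genes, which sort outer from inner cells in the early embryo, went both ways. Of 22 tested genes 6 were higher, 10 lower and 6 did not pass (6 and 10 adjusted over the list alone; median -0.34, camera adjusted p = 0.268; 0.547 with an estimated correlation). Wwc1 and Tead2 rose by 2.71 (SE 0.18) and 2.49 (SE 0.14), and the kinase gene Lats2 fell by 2.02 (SE 0.19). With the mean of a gene's probe sets Wwc1 gave 1.56 and Lats2 -1.20. The coactivator gene Wwtr1 fell by 1.68 (SE 0.14) on its brightest probe set, but gave 0.24 (adjusted p = 0.176) without the probe sets whose IDs end in _x_at, _s_at or _a_at.

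**Figure D3:**
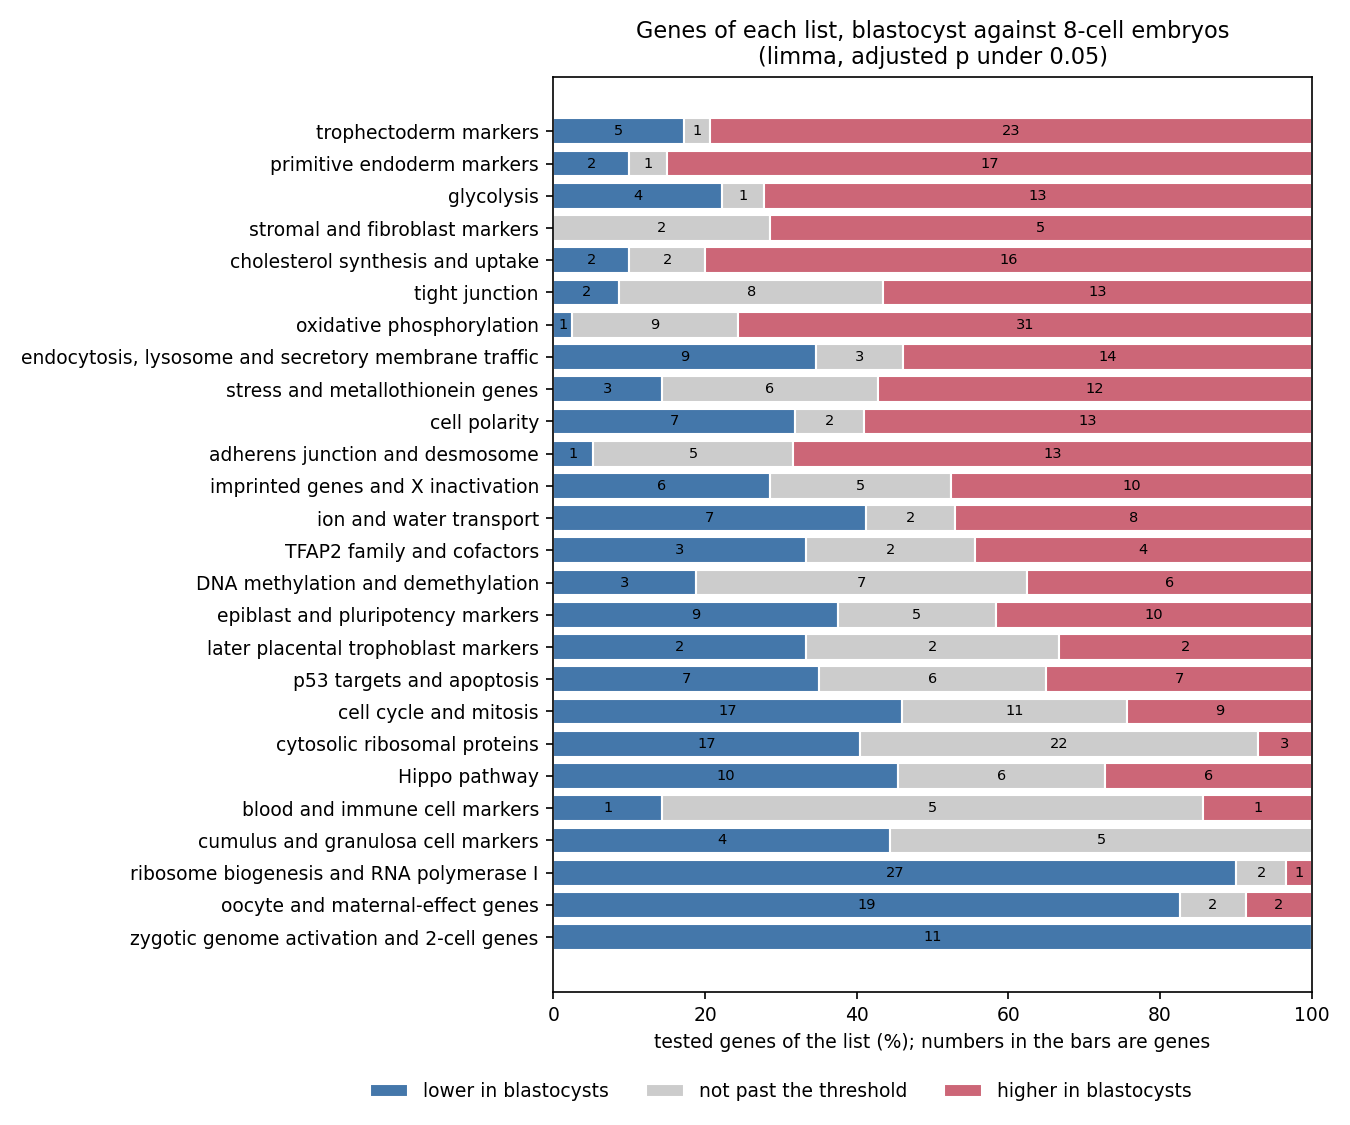
Share of the tested genes of each of the 26 lists (horizontal axis, percent) that were lower in blastocysts, not past the threshold or higher, with the number of genes in each bar and the lists ordered by median difference. Trophectoderm markers (23 of 29 higher) are at the top and zygotic genome activation genes (11 of 11 lower) at the bottom; on hybridisation spike-in scaling the medians of the cell cycle, p53 and later placental lists change sign.

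Genes of energy metabolism were mostly higher. Of 41 tested genes of oxidative phosphorylation 31 were higher, 1 lower and 9 did not pass (31 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 1.50e-05; adjusted p = 0.502 with an estimated correlation). The subunit genes of succinate dehydrogenase Sdhd and Sdhc rose by 3.56 (SE 0.12) and 3.33 (SE 0.20), and those of complex I Ndufa8 and Ndufb3 by 2.37 (SE 0.20) and 2.34 (SE 0.14). The lower gene, named after its value was seen, was Atp5pb (-0.39, SE 0.11). Of 18 tested glycolysis genes 13 were higher, 4 lower and 1 did not pass (13 and 4 adjusted over the list alone; median 1.84). Tpi1, encoding triose phosphate isomerase, rose by 4.92 (SE 0.17), while Hk1, a hexokinase gene (-4.73, SE 0.15), Ldhb, a lactate dehydrogenase gene (-3.18, SE 0.19), and Pfkfb3 (-6.09) fell. The remaining lower gene was Eno2 (-1.33, SE 0.23), named after its value was seen. The glycolysis list did not pass on the deposited scale (camera, adjusted p = 0.0662; 0.261 with an estimated correlation), and had an adjusted p = 0.0449 with quantile normalization. Cholesterol synthesis and uptake genes rose, with 16 of 20 higher, 2 lower and 2 not passing (16 and 2 adjusted over the list alone; median 1.10, camera adjusted p = 0.00426; adjusted p = 0.261 with an estimated correlation). Nsdhl rose by 4.56 (SE 0.25), and the mevalonate pathway genes Pmvk and Mvk by 3.37 (SE 0.13) and 3.13 (SE 0.18). The lower genes, named after their values were seen, were Fdft1 (-2.01, SE 0.14) and Lss (-0.80, SE 0.11), for steps between farnesyl diphosphate and lanosterol. Hsd17b7 rose by 2.61 (SE 0.17), but gave -0.10 (adjusted p = 0.742) without the probe sets whose IDs end in _x_at, _s_at or _a_at.

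Genes of ribosome assembly fell. Of 30 tested genes of ribosome biogenesis and RNA polymerase I 27 were lower, 1 higher and 2 did not pass (27 and 1 adjusted over the list alone; median -1.05, camera adjusted p = 6.02e-07; adjusted p = 0.104 with an estimated correlation). The largest falls were those of Wdr43 (-3.07, SE 0.11, from 18508 ± 779 to 2194 ± 199), Bop1 (-2.49, SE 0.15, or -1.54 with the mean of its probe sets), the polymerase subunit gene Polr1e (-2.42, SE 0.13) and Heatr1 (-2.38, SE 0.12). The higher gene was Nop56 (0.72, SE 0.14), named after its value was seen. Of 42 tested cytosolic ribosomal protein genes 17 were lower, 3 higher and 22 did not pass (17 and 3 adjusted over the list alone; median -0.30), among the lower genes Rps27 (-2.08, SE 0.27), Rpl39 (-1.15, SE 0.20) and Rpl37 (-0.96, SE 0.18). Rps24 fell by 0.99 (SE 0.12), but gave 0.16 (adjusted p = 0.424) on a probe set of another type. The higher genes, named after their values were seen, were Rpl14 (0.72, SE 0.15), Rpl41 (0.70, SE 0.15) and Rps6 (0.64, SE 0.21). The ribosomal protein list had an adjusted p = 0.00697 by camera, but 0.651 with an estimated correlation, 0.289 with quantile normalization and 0.137 with hybridisation spike-in scaling, where its median was -0.03.

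Cell cycle genes went both ways on the deposited scale (on hybridisation spike-in scaling the list median was above 0), with 9 of 37 tested genes higher, 17 lower and 11 not passing (9 and 17 adjusted over the list alone; median -0.27, camera adjusted p = 0.217; 0.544 with an estimated correlation). Ccne1 (-3.01, SE 0.15), Cdc25a (-2.18, SE 0.13) and Ccna2 (-1.81, SE 0.13, or -0.80 with the mean of its probe sets), which drive entry into and passage through S phase, fell, and the spindle checkpoint gene Bub1b rose by 1.59 (SE 0.13). Of 20 tested p53 targets and apoptosis genes 7 were higher, 7 lower and 6 did not pass (7 and 7 adjusted over the list alone; median -0.13, mean 0.27, camera adjusted p = 0.974; 0.986 with an estimated correlation). Ccng1 rose by 2.58 (SE 0.18), Zmat3 by 2.13 (SE 0.15), Perp by 2.10 (SE 0.36) and Casp9 by 1.97 (SE 0.22), or 0.73 with the mean of its probe sets. The lower genes included Aen (-1.47, SE 0.12) and Cdkn1a (-1.23, SE 0.18), named after their values were seen. Among 21 stress and metallothionein genes 12 were higher, 3 lower and 6 did not pass (12 and 3 adjusted over the list alone; median 0.75, camera adjusted p = 0.0961; 0.547 with an estimated correlation). The asparagine synthetase gene Asns rose by 3.37 (SE 0.18), Ddit3, a factor of the unfolded protein response, by 3.33 (SE 0.25) and the endoplasmic reticulum chaperone gene Hsp90b1 by 2.90 (SE 0.13). The heat shock gene Hspa1a fell by 3.44 (SE 0.40). This list had an adjusted p = 0.0304 with quantile normalization.

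Of 16 tested genes of DNA methylation and demethylation 6 were higher, 3 lower and 7 did not pass (6 and 3 adjusted over the list alone; median 0.27, camera adjusted p = 0.243; 0.547 with an estimated correlation). Mbd2, a reader of methylated DNA, rose by 3.73 (SE 0.29), the dioxygenase gene Tet2 by 3.63 (SE 0.16), the methylation cofactor gene Dnmt3l by 2.33 (SE 0.12) and Uhrf1, which directs maintenance methylation, by 2.30 (SE 0.12). The lower genes, named after their values were seen, were Tet3 (-1.70, SE 0.32), Dnmt3a (-1.32, SE 0.24) and Apex1 (-0.75, SE 0.15). Of 21 tested imprinted genes and X inactivation genes 10 were higher, 6 lower and 5 did not pass, and 11 and 6 were called when adjusted over the list alone (median 0.69, camera adjusted p = 0.383; 0.667 with an estimated correlation). The amino acid transporter gene Slc38a4 rose by 4.11 (SE 0.13), Sfmbt2 by 3.60 (SE 0.20) and the growth factor gene Igf2 by 3.25 (SE 0.17, or 2.03 with the mean of its probe sets), while Igf2r, encoding the receptor that clears it, fell by 3.08 (SE 0.14), from 9492 ± 706 to 1115 ± 176.

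Of 26 tested genes of endocytosis, lysosome and secretory membrane traffic 14 were higher, 9 lower and 3 did not pass (14 and 9 adjusted over the list alone; median 0.82, camera adjusted p = 0.217; 0.547 with an estimated correlation). The endocytic receptor genes Lrp2 and Cubn rose by 5.15 (SE 0.24) and 4.26 (SE 0.25), Rab25, encoding a GTPase of apical recycling, by 4.11 (SE 0.12) and the annexin gene Anxa2 by 3.78 (SE 0.16), or 1.39 with the mean of its probe sets. Lysosomal cathepsin genes were among the lower members, and Ctsz (-3.74, SE 0.16) and Ctsh (-3.53, SE 0.18) were named after their values were seen.

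Markers of other cells (cumulus and granulosa, blood and immune, stromal) and of later placental trophoblast were mostly dim, with Amhr2 and Fn1 among the exceptions. Of 21 listed cumulus and granulosa cell genes 9 were under the filter, with signals of 37.0 or less, 4 of 9 tested genes were lower in blastocysts and 5 did not pass (3 lower adjusted over the list alone; median -0.52, camera adjusted p = 0.134; 0.502 with an estimated correlation). Amhr2, encoding the receptor of anti-Müllerian hormone, was at 8118 ± 1598 in 8-cell embryos and 282 ± 36.8 in blastocysts (-4.76, SE 0.17). Kctd14 (-1.63, SE 0.20) and Inhbb (-1.58, SE 0.27) fell, and Foxl2 gave -0.47 (SE 0.17, adjusted p = 0.0335) and did not pass in 8 of 20 alternative settings. Of 7 tested blood and immune cell markers Lyz2 rose by 0.74 (SE 0.21, to 46.1 ± 6.65), Cd52 fell by 1.82 (SE 0.22) and 5 did not pass (1 and 1 adjusted over the list alone; median -0.40, camera adjusted p = 0.443; 0.547 with an estimated correlation). Of 7 tested stromal and fibroblast markers 5 were higher and 2 did not pass (5 adjusted over the list alone; median 1.20, camera adjusted p = 0.0917; 0.294 with an estimated correlation). They were led by fibronectin (Fn1, 3.68, SE 0.14, or 2.40 with the mean of its probe sets), Thy1 (2.21, SE 0.18), vimentin (Vim, 1.59, SE 0.27) and Pdgfrb (1.20, SE 0.13), while the fibroblast collagen gene Col1a1 was under the filter. The 8-cell signals of Thy1 and Pdgfrb were under the filter level of each array. With 64 added Thy1 gave 1.20 and Pdgfrb 0.55, and with 1 added Pdgfrb gave 2.00. Of 6 tested later placental trophoblast markers Plac8 rose by 2.67 (SE 0.18) and Rhox6 by 0.92 (SE 0.27), Flt1 (-2.24, SE 0.21, but -0.01 with 1 array left out and the probe set chosen anew) and Rhox9 (-2.04, SE 0.39) fell, and 2 did not pass (2 and 2 adjusted over the list alone; median -0.12, camera adjusted p = 0.874; 0.902 with an estimated correlation).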

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

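The tests on RNA length (in their present form), on a separate processing batch and on Ooep and Khdc3 were chosen after the results were seen.

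The 9517 genes called between the stages were compared with other groupings of the arrays. Only the real split, 1 of the 35 ways to part the 8 arrays into 4 and 4, gave as many, and the highest of the other splits gave 0. Every other split mixes both stages in each part, so the stage difference widens the spread there and leaves little to call. The comparison therefore adds nothing to the separation of the stages seen in the correlations. It also does not bear on a processing batch or on technical repeats.

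Trophectoderm and primitive endoderm markers were higher in blastocysts, and the 8-cell arrays carried the stronger 3' excess at Actb and Gapdh, so shorter amplified RNA could have lowered 8-cell signals. For 19 of 29 tested trophectoderm genes several probe sets passed the filter. The smallest difference among these probe sets of a gene had a median of 2.13 (95% bootstrap interval over genes 1.35 to 4.21). A probe set could pass through the blastocyst arrays alone, and those dim in both stages were left out, which can raise the smallest difference. The median argues against a loss at only some of the probe sets past the filter. The distance of the probe sets from the 3' end was not used, so a loss that reaches all of them stays open. The lowest list median over 4 scalings was 4.21, so the choice among these scalings does not account for the rise. For primitive endoderm the lowest list median was 3.36, and the same holds. Over 12 primitive endoderm genes, the smallest differences among probe sets past the filter had a median of 1.40. Its interval of 0.04 to 3.58 reaches below the limit of 0.5. RNA length in any form stays open there. A separate processing batch for each stage cannot be told apart from the stage, since 0 stages have arrays in both number formats. The developmental difference between the stages stays among the open explanations, untested against such a batch.

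Ribosome biogenesis genes were lower in blastocysts. The highest median over 4 scalings was -0.78, so the choice among these scalings does not account for the fall. None of them reads the amount of RNA per embryo, so the fall is relative to the other genes. Shorter RNA in the 8-cell arrays would lower signals there, but each array was scaled to the same mean, so a loss in other genes could raise these. It stays open. The highest difference among a gene's probe sets past the filter had a median of -0.83 over 20 genes (14 of them under -0.5). Its interval of -1.22 to -0.37 reaches the limit of -0.5, so the values do not decide. A separate processing batch for each stage (0 stages with both number formats) stays open too, as does the developmental difference.

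Ooep and Khdc3 were higher in blastocysts, while 19 of the 23 tested maternal genes were lower. A mislabelled or swapped array is argued against by the correlations over all probe sets, since each array's lowest correlation with its own stage exceeded its highest with the other stage by 0.105 or more. A change shared with neighbouring genes stays open. Of the 20 nearest tested genes (5 on each side of each gene) 6 were higher, against 37.5% of all tested genes (exact one-sided binomial test, p = 0.821), but this definition replaced, after its result was seen, one that also took the genes between the pair (17 of 38 higher, p = 0.224). A separate processing batch was not tested for this pair, and the developmental difference stays open.

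In 20 of 292 groups of 4 arrays, formed by the named genes and the array measures, 1 array lay far from the others by Dixon's gap test. Chance gives about 1 in 20 groups. Replicate 4 of the blastocysts was the far array in 7 of them and replicate 4 of the 8-cell embryos in 5. Blastocyst replicate 4 had B3gnt5 at 6290 (others 9830 to 10200), Pfkfb3 at 30.6 (3.31 to 6.08), Dsg2 at 6300 (6500 to 6560), Pkp2 at 6120 (5210 to 5320), Rps27 at 254 (102 to 117), Ccne1 at 2000 (1460 to 1540) and Anxa2 at 8000 (7150 to 7260). Replicate 4 of the 8-cell embryos had Tceal9 at 6.9 (66.6 to 79.1), Sparc at 113 (6.1 to 12.3), Polr1e at 3250 (2640 to 2720), Cdc25a at 7170 (9250 to 9550) and Asns at 630 (874 to 934). Other 8-cell arrays had Dsc2 at 25.2 (replicate 1, others 3.5 to 6), Dnmt3l at 493 (replicate 1, 424 to 434), Lama1 at 32.2 (replicate 2, 22.1 to 23.6), Rhox9 at 119 (replicate 2, 464 to 478) and Pard6b at 329 (replicate 3, 480 to 494). Other blastocyst arrays had Sox17 at 2890 (replicate 1, 3480 to 3580), Lama1 at 4330 (replicate 1, 2560 to 2670) and Lyz2 at 56 (replicate 2, 41.9 to 43.6).

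Probe sets without a gene name also differed between the stages. Of 3844 tested, 1870 passed an adjusted p of 0.05 (limma), 873 higher and 997 lower in blastocysts. The largest rise among them was 7.66 log2 units (12.2 to 5528) and the largest fall -7.34 (3836 to 8.11), both with a signal under the filter level in 1 stage, so their size and rank depend on the added 16.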

How the results depend on the processing

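Of the alternatives, scaling to the hybridisation spike-ins and the rule to keep the tested genes and probe sets were chosen after the data were seen. Over 20 alternatives the counts of higher and lower genes, and of those changed at least 2-fold, stayed within 1.5 times their main values, and leaving out each array gave 4783 to 4880 higher and 4331 to 4507 lower genes. Tfap2c stayed lower throughout, at -1.37 to -1.21 without each array in turn and at -0.71 without probe sets ending in _x_at, _s_at or _a_at. The replicate numbers do not pair the arrays (correlations of same-numbered deviations -0.02, -0.03, -0.03 and -0.04, and no array correlated best with its own number); with the replicate block 4862 genes were higher and 4412 lower. Of 20 settings for each of the 140 named genes, 29 combinations had no value because the gene did not pass the filter or had no probe set left. Where a cause is not given below, it was not tested. No detection calls were used, so differences between signals in the lower part of an array are the least certain.

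No list changed its side of the threshold when an array was left out, with glycolysis at adjusted p 0.0546 to 0.0818, cell polarity at 0.139 to 0.192, tight junction at 0.0141 to 0.0320 and ribosomal proteins at 0.00199 to 0.0254. With the filter and choice of probe set repeated on the 7 arrays left, glycolysis was at 0.0310 to 0.0484 and cell polarity at 0.0436 to 0.135. The filter asks for 4 arrays, so genes dim in the stage that kept its 4 arrays drop out of that version. Glycolysis passed with quantile normalization (adjusted p = 0.0449), no filter (0.0161), without probe sets ending in _x_at, _s_at or _a_at (0.0128) and with trend and robust estimation (0.0457). Stress genes passed with quantile normalization (0.0304) and no filter (0.0459), and stromal markers without those probe sets (0.0404). Ribosomal proteins did not pass with quantile normalization (0.289), without those probe sets (0.106) or with spike-in scaling (0.137), and tight junction not with a filter at the 60th percentile (0.0533).

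None of the 10 lists that camera called held with an estimated correlation: adherens junction, trophectoderm, zygotic activation and ribosome biogenesis had an adjusted p of 0.104 each, tight junction 0.144, maternal genes 0.153, primitive endoderm 0.251, cholesterol 0.261, oxidative phosphorylation 0.502 and ribosomal proteins 0.651. Among these lists the estimated correlation was highest for ribosomal proteins (0.67) and oxidative phosphorylation (0.42). It lay below the preset 0.01 for tight junction (-0.013) and adherens junction (0.0075), where correlation does not account for the weaker result. Fry, which does not compare a list with other genes, called in addition cell polarity (1.85e-07), stromal markers (6.19e-06), glycolysis (3.07e-06), endocytosis (9.08e-06), ion and water transport (1.12e-05), DNA methylation (1.32e-05), cell cycle (0.000138), stress (0.000138), cumulus markers (0.000392), imprinted genes (0.00042), Hippo (0.0152) and blood markers (0.0384).

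Without probe sets ending in _x_at, _s_at or _a_at, 4 named genes changed sign because another probe set stood for the gene: Prkci (-0.0576), Wwtr1 (0.24), Rps24 (0.16) and Hsd17b7 (-0.10). With the probe set chosen anew on 7 arrays, Wwtr1 ran from -1.72 to 0.33, Hsd17b7 from -0.26 to 2.71 and Flt1 from -2.39 to -0.01. With the mean of a gene's probe sets, 23 of 135 called named genes moved by over 1.5 times and kept their sign, among them Exoc3l2 (-3.45), Cgnl1 (1.84), Lsr (2.26), Patj (2.17), Tfcp2l1 (1.19), Cited4 (1.16), Anxa2 (1.39), Casp9 (0.73), Ccna2 (-0.80) and Hsd17b7 (0.60). Exoc3l2, Lsr, Tfcp2l1 and Cited4 had 0 other probe sets past the filter, so their means were drawn down by dim probe sets. When an array was left out, 0 of 137 moved as far. Without probe sets ending in _x_at, _s_at or _a_at 7 of 116 moved as far, the 4 that changed sign and Id2 (4.09), Acsl4 (-3.97) and Lats2 (-0.94). Tfap2c, which is left out of these counts, also moved by over 1.5 times there, from -1.28 to -0.71. With spike-in scaling 3 did, Foxl2 (-0.22), Gata6 (-0.29) and Cdh1 (0.74), and with 1 added 2 did, Lyz2 (1.15) and Pdgfrb (2.00). With 64 added 10 did, Cited4 (1.82), Casp9 (1.27), Rab25 (2.74), Kctd14 (-1.05), Cd52 (-1.13), Lyz2 (0.36), Thy1 (1.20), Pdgfrb (0.55), Flt1 (-1.23) and Rhox6 (0.51). Gata6 did not pass with spike-in scaling, Foxl2 in 8 settings, and Cldn6 passed in 3.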

Other observations

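The gene families in this part, the genes named in them and the test on starting levels were chosen after the data were seen. Among 30 families defined by gene symbol, those of transcription machinery fell (camera, adjusted over the families; directions the same under 4 scalings). Of 25 tested RNA polymerase subunit genes 18 were lower and 4 higher (median -1.05, adjusted p = 0.00491; 0.123 with an estimated correlation; 4 of them in the fixed lists), with Polr3a and Polr3k, of RNA polymerase III, at -2.91 (SE 0.14) and -2.64 (SE 0.11). Of 20 TBP-associated factor genes 16 were lower and 0 higher (median -1.04, adjusted p = 0.0026; 0.194 with an estimated correlation), among them Taf1a (-3.01, SE 0.12) and Taf1c (-2.69, SE 0.14), which serve RNA polymerase I. Mediator subunits (18 of 30 lower, adjusted p = 0.0486; 0.194 with an estimated correlation), DEAD- and DEAH-box helicases (31 of 51 lower, adjusted p = 0.0101; 0.194) and translation initiation factors (26 of 46 lower, adjusted p = 0.00747; 0.424) went the same way, with Med30 (2.69, SE 0.13) among the higher genes. Nlrp genes fell too (10 of 11 lower, median -1.90, adjusted p = 0.00491; 0.123 with an estimated correlation), 3 of them being in the maternal list.

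Annexins, which bind membranes with calcium, rose (7 of 9 higher, 0 lower, median 3.17, adjusted p = 0.00747; 0.123 with an estimated correlation; 4 of them in the fixed lists). Anxa6 went from 39.8 to 5611 (6.70, SE 0.23) and Anxa3 rose by 3.45 (SE 0.12). Glutathione transferases rose as well (12 of 17 higher, 2 lower, median 2.22, adjusted p = 0.00747; 0.123 with an estimated correlation), with Gsta4 at 5.25 (SE 0.15, 351 to 13700) and Gstk1 at 4.96 (SE 0.33). Laminin chains rose (6 of 8 higher, median 2.49, adjusted p = 0.0389; 0.242 with an estimated correlation), 3 of them being in the primitive endoderm list. Proteasome subunits went both ways (17 higher and 16 lower of 47, adjusted p = 0.944).

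The control probe sets for the transferrin receptor fell (-5.76 at the 3' end, -3.57 in the middle and -2.55 at the 5' end), and those for Gapdh rose by 4.29, 4.89 and 5.25 in the same order (exact permutation test, p = 0.0286 each, the smallest possible; adjusted p = 0.0352 over the control probe sets). A control probe set for the mouse B1 repeat (-1.85) and the pair for the B2 repeat (-3.04 and -0.43) also fell, as did the 5' set for 18S ribosomal RNA (-0.41), and the Actb sets rose (1.04 at the 3' end, 2.28 in the middle and 2.64 at the 5' end; same test and p). The 3' set for 18S differed by 0.33 and did not pass (exact permutation p = 0.0857, adjusted p = 0.098).

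Of the tested trophectoderm genes 23 of 29 rose, and of the pluripotency genes 10 of 24, a comparison set up after these counts were seen. The median 8-cell signal of the pluripotency genes was 1350 against 190 for the trophectoderm genes (two-sided permutation test with 100000 resamples that takes genes as independent, p = 0.00499). Whether a higher starting level accounts for the smaller share that rose stays open, since the 8-cell signal is itself part of the difference. The arrays read whole embryos, so the share of cells of each lineage was not tested and stays open too.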
